A study of Drosophila melanogaster with 6 samples.

How the data were processed

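Gcn5 binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in 2 Drosophila melanogaster cell lines, Kc and S2. Gcn5 is a histone acetyltransferase, the catalytic subunit of the SAGA and ATAC coactivator complexes. CP190 is a zinc-finger protein with a BTB domain that is recruited to chromatin insulators and to many promoters. Per the labels' protocols, cells received 90 µg of double-stranded RNA per 6000000 cells, against GFP as the control or against CP190, and each immunoprecipitation used 5 µg of a rabbit polyclonal Gcn5 antibody on formaldehyde-crosslinked chromatin. The series has 6 samples, of which 3 are Gcn5 libraries with a peak list each: Kc with GFP RNAi, Kc with CP190 RNAi, and S2 with GFP RNAi. The other 3 are the matching input libraries, which were not analysed here. Groups were taken from the sample titles.

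Per the submitters' processing notes, the genome build was dm3 and the tools were Bowtie, MACS, bedtools and HOMER. Their versions, the role of each tool, the peak threshold and the use of the inputs are not given in the sources used here. The deposited values are 1 peak list per library, with a sequence name, start, end, peak name and a score per peak. The score is the authors' own value from the peak caller, with no normalization between libraries. The lowest score of each list lies at or just above 50, which is the form of 10 times the negative log10 of a p-value in MACS 1.4, but the files do not state the scale. Scores were therefore used only to rank, bin or filter peaks within a list, never to compare binding strength between libraries. The S2 list holds 8 peaks at a score of exactly 3100. The lists contain no read counts or coverage, so the sequencing depth is unknown. A peak absent from a list is one that was not called, which does not show that Gcn5 was absent from the site. A deeper or better enriched library calls more peaks, so every count below also depends on depth and enrichment that cannot be seen here.

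The sequence names of the Kc lists carry a prefix that the S2 list lacks. It was removed, and both spellings gave the names of the dm3 build. Positions are printed 1-based on dm3, with the list's starts taken as 0-based as in the BED format. No annotation or genome of dm3 was used here, and the gene table at hand belongs to assembly Release 6. Peaks were therefore not assigned to genes, and the comparisons of promoters, fixed gene lists and sequence motifs that had been planned on condition of a dm3 reference were not run.

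No list held overlapping peaks. A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. Shares are given with exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Each overlap was set beside 1000 circular shifts of the other list within each sequence, each sequence taken as long as the farthest peak end in the 3 lists. Peaks were binned into 5 quintiles by score or by width within their own list. Differences between shares of peaks are given with a 95% bootstrap interval over 1000 resamples of 1 Mb blocks, which covers the spread between regions of these lists and not between libraries. Differences within quintiles were averaged with weights equal to the number of peaks. Regional values used windows of 100 kb on the major arms (X, 2L, 2R, 3L, 3R and 4) with at least 10 Kc GFP RNAi peaks. Whether neighbouring peaks had the same fate was compared with 1000 permutations of the fates among peaks of the same score quintile, width quintile and S2 status.

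Each condition has 1 library. No difference between conditions has a replicate check, no p-value is given, and peaks are not replicates. No paired or leave-one-out fit exists for such a design. The main comparisons, their alternatives and the rule for named peaks were fixed before the data were examined. For each pair of lists the rule named the 10 highest-scored peaks on the major arms that were found only in the first list, the 10 found only in the second and the 10 of the first list that were shared. It also named the 3 windows with the highest and the 3 with the lowest share of missing peaks, with ties. The splits by peak width and the comparison of neighbouring peaks were added after the data were seen, as were the intervals for dense windows. The fixed comparisons also did not include the counts among the highest-scored peaks or the split of S2 peaks by Kc list. Nor did they include the S2 status of CP190 RNAi peaks with and without a control peak. Alternatives covered the overlap rule (50% of the counted peak, 50% reciprocal, centres within 250 bp, or peaks within 1000 bp), the score threshold (100 or more), lists of equal length, the major arms alone and peaks merged across gaps of 200 bp.

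The overlap calculation was tested on simulated data in which a random part of the 5096 Kc GFP RNAi peaks was removed and the rest moved by up to 100 bp. The kept share was recovered within 0.098 percentage points, and the narrowest and widest quintiles differed by at most 3.66 points where no difference had been built in. Widths were unchanged and the narrowest peak was 415 bp, so each kept peak still overlapped itself. The simulation therefore could not test a width bias from changed widths or larger moves. Counts of overlapping peaks were also checked against bedtools 2.31.1. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.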

Results

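Gcn5 ChIP-seq peak lists from 3 libraries were compared. Kc and S2 are cell lines derived from Drosophila embryos. The Kc GFP RNAi list held 5096 peaks with a median width of 1271 bp, covering 7.98 Mb. The Kc CP190 RNAi list held 4228 peaks with a median width of 1308 bp, covering 6.69 Mb. The S2 GFP RNAi list held 5062 peaks with a median width of 1209 bp, covering 7.64 Mb. Each condition was represented by 1 library, so none of the differences below has a replicate check. Read depth is unknown for all 3.

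The peaks were spread over all chromosome arms in each library. Their number differed most in proportion between the Kc lists and the S2 list on chromosome 4 and on the unplaced sequences. S2 also had more peaks than the Kc control on 2L (979 against 844) and 3L (1024 against 913). The S2 list names its sequences differently, so a difference in processing cannot be told apart from one between the cell lines. On chromosome 4, a small and largely heterochromatin-like chromosome, S2 cells had 119 peaks, or 2.35% of the list (95% interval 1.95 to 2.81%). The Kc libraries had 53 peaks there with GFP RNAi (1.04%, 0.780 to 1.36%) and 42 with CP190 RNAi (0.993%, 0.717 to 1.34%). On the unplaced sequences U and Uextra the order was the opposite, with 401 Kc GFP RNAi peaks, 383 Kc CP190 RNAi peaks and 21 S2 peaks. The X chromosome held 842 Kc GFP RNAi peaks, 716 Kc CP190 RNAi peaks and 846 S2 peaks, which was 16.5%, 16.9% and 16.7% of the lists.

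**Figure D1:**
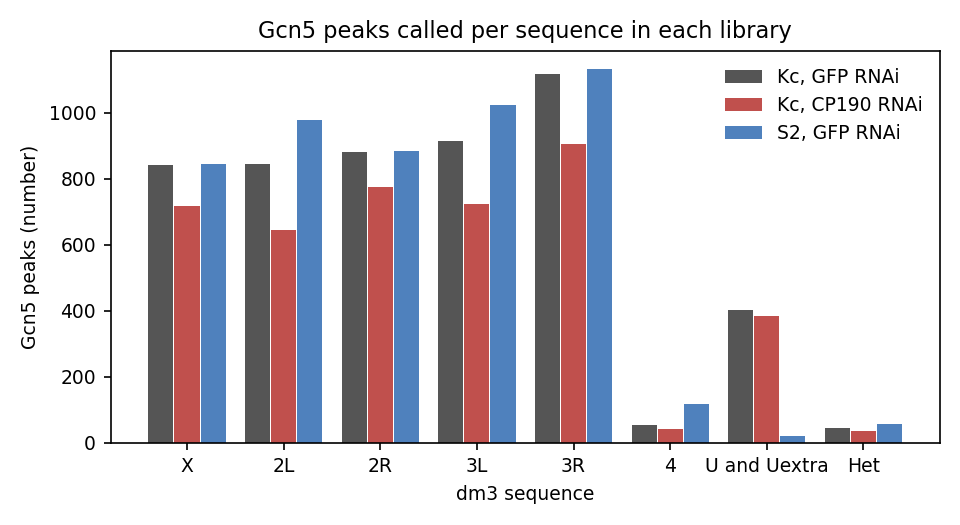
Number of Gcn5 peaks (vertical axis) on each dm3 sequence (horizontal axis) in the 3 libraries, with U and Uextra and all Het sequences pooled. S2 cells had 119 peaks on chromosome 4 against 53 and 42 in the Kc libraries, and 21 peaks on U and Uextra against 401 and 383.

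The series' title and design ask how far Gcn5 binding in Kc cells depends on CP190. After CP190 RNAi, 2152 of the 5096 Gcn5 peaks of the control library had no overlapping peak, a share of 42.2% (40.9 to 43.6%). The remaining 2944 control peaks (57.8%, 56.4 to 59.1%) were still met by a peak. The CP190 RNAi list also held 1250 peaks that the control list lacked, which was 29.6% of its 4228 peaks (28.2 to 31.0%). Randomly placed lists of this size would share far less, since 1000 circular shifts of the CP190 RNAi list met a median of 9.24% and at most 11.3% of the control peaks. The shifts do not show how much a ChIP-seq list of another protein would share.

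Control peaks were missing after CP190 RNAi at every score level, the strongest peaks included. In the lowest score quintile 55.1% of the control peaks had no CP190 RNAi peak (52.0 to 58.2%), and the share was 33.8% in the fourth (30.9 to 36.8%). In the highest quintile it was 41.0% (38.0 to 44.1%). Of the 100 highest-scored control peaks on the major arms, 50 were missing (39.8 to 60.2%). The missing share was 3 of the highest 10 and 44.0% of the highest 500 (39.6 to 48.5%). The peaks found only after CP190 RNAi behaved otherwise, with a share of 53.8% in the lowest score quintile of their list (50.4 to 57.2%) and 4.73% in the highest (3.40 to 6.38%). Of the 100 highest-scored CP190 RNAi peaks on the major arms, 2 had no control peak (0.243 to 7.04%).

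The strongest missing site lay at 3R 13440532 to 13443907 and had a score of 1789.14, the highest of the control list. Of the next 9 sites by score, 2 lay on chromosome 4, at 1133056 to 1134734 with a score of 1372.92 and at 854826 to 857099 with a score of 1206.67. The site at X 15956386 to 15958155 had a score of 1292.69. The 3R sites at 5693514 to 5695503 and at 793747 to 797428 had scores of 1213.81 and 1200.64. The 2R sites at 16771436 to 16772782 and at 12494407 to 12498583 had scores of 1190.22 and 1189.04. The sites at X 17425546 to 17427162 and at 3R 12481017 to 12482620 completed the 10 strongest missing sites. All 10 had a Gcn5 peak in S2 cells.

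Sites of comparable strength were kept. The strongest control site that was also called after CP190 RNAi lay at 3L 14182451 to 14184659, with a score of 1724.78. The sites at 2R 1902545 to 1905867 (score 1433.34), 2R 21069933 to 21071349 (1391.87), 3L 3221708 to 3227045 (1330.11) and 3L 9503572 to 9505728 (1315.46) followed. The 10 strongest kept sites had scores down to 1025.04, and all 10 had a peak in S2 cells too. Genes are not named for these sites because no dm3 annotation was used here.

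Among sites called only after CP190 RNAi, 1 stood far above the rest. It lay at 3R 7779521 to 7783003, was 3483 bp wide and had a score of 937.88. The next were at X 457405 to 459830 with a score of 477.14 and at 3L 7856053 to 7861322 with a score of 395.79. The site at 2L 22353455 to 22355338 had a score of 366.21. The 10 strongest such sites had scores down to 288.97, and 4 of them had a peak in S2 cells.

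Kept and missing control peaks differed in shape. Missing peaks had a median width of 1111 bp (quartiles 987 and 1339 bp), and kept peaks 1480 bp (1177 and 2067 bp). In the narrowest width quintile, up to 1025 bp, 70.4% of control peaks were missing (67.5 to 73.2%), against 18.2% in the widest, from 1953 bp (15.8 to 20.7%). On the major arms these shares were 82.4% (79.4 to 85.1%) and 17.7% (15.4 to 20.3%). Within score quintiles the narrowest and widest peaks on the major arms differed by 63.1 points (bootstrap interval 58.3 to 67.9). In the narrowest quintile on the arms, 83.2% of the weakest 304 peaks and 82.9% of the strongest 41 peaks were missing. Over all sequences these shares were 79.2% and 51.9%. Off the arms, 39.0% of the 282 narrowest peaks were missing (33.3 to 45.0%), as were 24 of 83, 9 of 41 and 5 of 25 peaks in the next 3 quintiles. The widest quintile there held 16 peaks, of which 43.8% were missing (19.8 to 70.1%). Among the strongest peaks on the arms, 15.5% of the 322 widest were missing. The split by width differed between comparisons. On the major arms, 34.0% of the narrowest and 32.0% of the widest Kc control peaks had no S2 peak, a difference of -12.6 points within score quintiles (narrow minus wide, -17.4 to -7.66). Over all sequences these shares were 50.9% and 32.8%, and the difference turned to 8.76 points (1.07 to 16.9). Of the S2 peaks on the major arms, 63.6% of the narrowest and 27.4% of the widest had no Kc control peak, a difference of 18.8 points within score quintiles (12.9 to 23.9). Of the CP190 RNAi peaks on the major arms, 35.7% and 24.2% had no control peak (-4.83 points within score quintiles, -10.2 to 1.28). Wide peaks also meet another list more often by position alone, by 6.88 points between the outer quintiles under circular shifts.

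**Figure D2:**
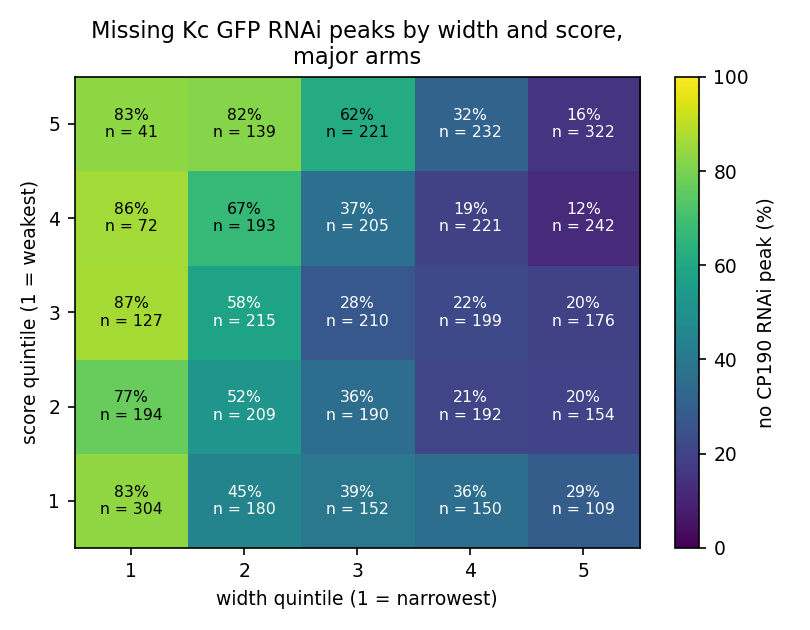
Percentage of Kc GFP RNAi Gcn5 peaks on the major arms with no overlapping CP190 RNAi peak (colour and number in each cell, with the number of peaks n), by width quintile (horizontal axis) and score quintile (vertical axis) of the whole control list. Shares in the narrowest column lie between 76.8% and 86.6%, and those in the widest between 12.4% and 29.4%.

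The missing share varied less between chromosome arms than with width. It was highest on 2L, where 393 of 844 control peaks were missing (46.6%, 43.16 to 49.996%), and lowest on X, with 324 of 842 (38.5%, 35.2 to 41.9%). The pooled autosomal arms stood at 43.9% (42.4 to 45.5%). X lay below the autosomal arms, with a difference of -5.47 points (X minus autosomal arms, bootstrap interval -11.0 to -0.36), and within score quintiles the interval included 0 (-10.5 to 0.093). Within score and width quintiles it was -5.00 points (-10.2 to -0.44). On chromosome 4, 21 of 53 control peaks were missing (39.6%, 26.5 to 54.0%). On U and Uextra 136 of 401 were missing (33.9%, 29.3 to 38.8%).

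Regions dense in Gcn5 peaks had a lower missing share. The 25 windows of 100 kb with at least 10 control peaks held 261 peaks, of which 31.4% were missing (25.8 to 37.4%), against 43.6% of the 4388 peaks elsewhere on the arms (42.2 to 45.1%). The difference was -12.2 points (dense minus other windows, bootstrap interval -19.3 to -4.01), and -8.73 points within score quintiles, width quintiles and S2 status (-14.2 to -2.82). Overlap by position alone was not computed by peak density. A higher chance of meeting any CP190 RNAi peak in dense windows can therefore not be told apart from better keeping of sites. The best kept windows were 2R 8000001 to 8100000 and 3L 9400001 to 9500000, each with 1 of 11 peaks missing, and 3R 25800001 to 25900000 and X 11400001 to 11500000, each with 1 of 10. The window with the largest missing share was X 16700001 to 16800000, with 7 of 10. It was followed by 2L 16300001 to 16400000, 3L 1800001 to 1900000 and 3R 15700001 to 15800000, each with 6 of 10. With 10 or 11 peaks per window the exact intervals of these extremes overlap (up to 44.5% for 1 of 10, and from 34.8% for 7 of 10).

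The second comparison asks which Gcn5 sites are common to Kc and S2 cells under the control treatment. Of the Kc control peaks, 3043 of 5096 overlapped an S2 peak (59.7%, 58.4 to 61.1%), and of the S2 peaks, 3058 of 5062 overlapped a Kc control peak (60.4%, 59.0 to 61.8%). Circular shifts gave medians of 11.3% and 11.6%, and none of the 1000 shifts reached either observed share. The strong sites were mostly common to both lines. In the highest score quintile 87.0% of Kc peaks had an S2 peak (84.8 to 89.0%) and 93.4% of S2 peaks had a Kc peak (91.7 to 94.8%), against 36.6% (33.6 to 39.6%) and 31.0% (28.2 to 33.9%) in the lowest. Among the 100 highest-scored peaks of either line on the major arms, 1 was found in that line alone.

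Sharing between the cell lines varied with the sequence. Of the 53 Kc control peaks on chromosome 4, 49 were also S2 peaks (92.5%, 81.8 to 97.9%), whereas 69 of the 119 S2 peaks there had no Kc peak (58.0%, 48.6 to 67.0%). Of the 401 Kc peaks on U and Uextra, 17 had an S2 peak (4.24%, 2.49 to 6.70%). On the Het sequences 24 of 46 Kc peaks had an S2 peak (52.2%, 36.9 to 67.1%), and 33 of 57 S2 peaks had no Kc peak (57.9%, 44.1 to 70.9%). On the major arms alone, 64.6% of the Kc peaks were shared with S2 (63.2 to 65.9%).

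On the major arms of Kc cells the strongest peaks without an S2 counterpart scored below the strongest shared ones. The 10 strongest shared sites had Kc scores from 1267.06 to 1789.14. On the major arms, the strongest Kc site without an S2 peak lay at 3R 8327373 to 8333609, was 6237 bp wide and had a score of 837.09. The wider CP190 RNAi peak over it, at 3R 8327361 to 8337358, did overlap an S2 peak. The next Kc control sites were 3L 24456928 to 24458022 with a score of 630.76 and X 21228453 to 21229936 with a score of 587.41. Of the 10 strongest such Kc sites, 6 were kept after CP190 RNAi. The strongest S2 site without a Kc control peak lay at 2L 9656891 to 9658089, with a score of 1944.77 in the S2 list. The sites at 2R 10434185 to 10435678 (1298.72), 2L 16846732 to 16849428 (1113.18) and X 12552521 to 12554112 (1077.76) came next. The site at 4 679278 to 685806, with an S2 score of 944.24 and no Kc control peak, overlapped a CP190 RNAi peak at 4 679280 to 682644.

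Setting the 3 lists together showed that the Kc control peaks shared with S2 were the ones more often missing after CP190 RNAi. Of the 3043 control peaks with an S2 peak, 1457 were missing (47.9%, 46.1 to 49.7%), against 695 of the 2053 without one (33.9%, 31.8 to 35.9%). The difference was 14.03 points (bootstrap interval 10.2 to 17.5), and it was 21.0 points within score quintiles (17.6 to 24.3). It was largest in the fourth score quintile, where 43.5% of the 704 S2-shared peaks (39.8 to 47.2%) and 12.1% of the 315 others (8.68 to 16.2%) were missing. In the highest score quintile 44.6% of the 887 S2-shared peaks were missing (41.3 to 48.0%), against 16.7% of the 132 peaks without an S2 peak (10.7 to 24.1%). In the lowest quintile these shares were 59.2% (54.1 to 64.3%) and 52.7% (48.8 to 56.6%). Peaks shared with S2 had a median width of 1307 bp, and those not shared 1216 bp. Averaged within score and width quintiles together the difference was 21.0 points (17.7 to 24.1), and on the major arms 16.9 points (13.7 to 20.2). The difference varied with width. In the narrowest width quintile 87.6% of S2-shared peaks (84.4 to 90.4%) and 53.8% of the others (49.4 to 58.1%) were missing, in the fourth 29.5% (26.0 to 33.3%) and 19.4% (15.6 to 23.6%), and in the widest 17.4% (14.6 to 20.4%) and 19.8% (15.6 to 24.4%). The narrowest quintile on the major arms alone gave 89.3% (86.2 to 91.9%) and 68.9% (62.8 to 74.6%), and the gap was larger in the second quintile, at 70.5% (66.6 to 74.1%) and 40.8% (35.6 to 46.2%).

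**Figure D3:**
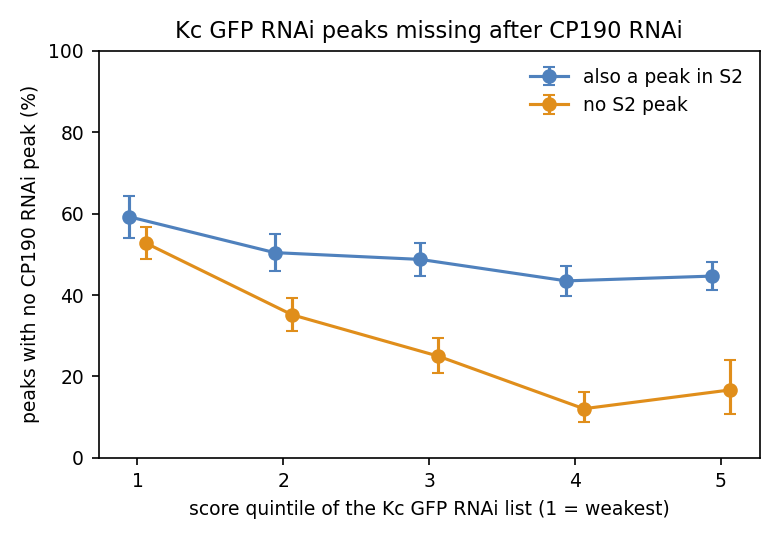
Percentage of Kc GFP RNAi Gcn5 peaks with no overlapping CP190 RNAi peak (vertical axis) by score quintile of the control list (horizontal axis), for peaks with and without an S2 peak. Points are shares and bars are exact 95% binomial intervals, which cover counting error only. In the highest quintile the shares are 44.6% and 16.7%.

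Counted from the S2 list, overlap with the control list alone was more frequent than overlap with the CP190 RNAi list alone. Of the 5062 S2 peaks, 1594 overlapped both Kc lists (31.5%, 30.2 to 32.8%), 1464 the control list alone (28.9%, 27.7 to 30.2%) and 281 the CP190 RNAi list alone (5.55%, 4.94 to 6.22%). The remaining 1723 overlapped neither. In the highest score quintile of the S2 list, 571 of 1013 overlapped the control list alone (56.4%, 53.2 to 59.4%) and 11 the CP190 RNAi list alone (1.09%, 0.543 to 1.93%). Of the 1250 peaks called only after CP190 RNAi, 294 had an S2 peak (23.5%, 21.2 to 26.0%). Of the 2978 CP190 RNAi peaks shared with the control, 53.5% had one (51.6 to 55.3%).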

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

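The differences by S2 status, by width after CP190 RNAi and between X and the autosomes kept their direction under the alternatives given here. The narrow minus wide difference of Kc control peaks without an S2 peak did not, at -12.6 points on the major arms and 8.76 points over all sequences. The X against autosome difference stayed within its bootstrap interval under all 4 of its alternatives. The score threshold moved both unshared shares most, and the overlap rule both shares common to the lines. With centres within 250 bp, 50.5% of control peaks and 40.4% of CP190 RNAi peaks were unshared, and 46.6% of Kc and 46.9% of S2 control peaks were common to the lines. A 50% reciprocal overlap gave 44.4%, 32.9%, 54.1% and 54.4% in the same order, and peaks within 1000 bp gave 39.4%, 26.0%, 62.4% and 64.4%. Covering 50% of the counted peak moved the Kc and S2 common shares to 57.3% and 58.1%. A score of 100 or more was met by 3340 of the 5096 control peaks and 2343 of the 4228 CP190 RNAi peaks, so the cut was not equally strict. With both lists at that score, 54.5% of control and 34.5% of CP190 RNAi peaks were unshared. With the threshold on the counted list alone these were 38.3% and 15.6%, and the common shares were 69.6% in Kc and 73.3% in S2. Lists of equal length gave 39.4% and 38.6% unshared, which are close by construction. The major arms alone gave 64.6% of Kc peaks common to S2. The excess of missing peaks among S2-shared sites was 24.4 points with control peaks at a score of 100 or more, 21.0 points within score quintiles and 21.0 points within score and width quintiles. The excess among narrow over wide peaks was 25.1 points with centres within 250 bp, 46.1 points with reciprocal overlap, 46.0 points at a score of 100 or more in both lists, 64.6 points on the major arms and 45.4 points within score quintiles. The width alternatives and the average over score and width quintiles were chosen after seeing the data. No paired analysis was possible because each condition has 1 library. The planned promoter and gene list comparisons were not run, since no dm3 annotation was used here. Depth is unknown, so a missing peak is a site not called in that library.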

Other observations

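The tests of weak signal, narrow peaks in general, unplaced sequences, width and score, and of the single libraries were chosen after the results were seen, as was the neighbour comparison; those of chance overlap and of blurring were written before their values were seen. The strongest peak of the CP190 RNAi list lay at 3R 8327361 to 8337358, was 9998 bp wide and had a score of 3195.85, against 1270.96 for the next peak of that list, at 3L 3191868 to 3199888. The control list had a peak at the same place, 3R 8327373 to 8333609, which was 6237 bp wide and was the strongest Kc control peak on the major arms with no S2 peak. The wider CP190 RNAi peak did overlap an S2 peak. The strongest peak found only after CP190 RNAi, at 3R 7779521 to 7783003, lies on the same arm. These 2 sites were singled out after their values were seen.

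Neighbouring control peaks tended to have the same fate after CP190 RNAi. On the major arms 60.2% of 4643 neighbouring pairs were both kept or both missing, above the median of 53.8% and the highest value of 55.8% in 1000 permutations that held score, width and S2 status. The share was 65.7% for the 895 pairs under 5000 bp apart (permuted median 54.9%) and 63.0% for the 2008 pairs from 5000 to 20000 bp (54.8%). For the 1122 pairs from 20000 to 50000 bp it was 57.1%, which 1 permutation reached. For the 618 pairs over 50000 bp apart it was 48.9%, and 856 of the 1000 permutations were as high.

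The first pattern is the loss itself, with 42.2% of control peaks not called after CP190 RNAi. Lower depth or enrichment of that library would remove weak peaks first. The share missing in the highest score quintile was 41.0%, with a lower bound of 38.0%, above the limit of 10% set for weak signal. That limit was chosen after the value was seen and rests on no depth value. Loss among the strongest peaks argues against weak signal as the whole cause, though weak signal may add to the 55.1% missing in the lowest quintile. In the highest quintile on the major arms, 82.9% of the narrowest and 15.5% of the widest peaks were missing. A loss of narrow peaks through lower enrichment is therefore not excluded. Any other difference between the 2 libraries, in preparation or in knockdown, cannot be told apart from CP190 depletion, because there is 1 library per condition. CP190 depletion, the difference the design names, stays open as an explanation.

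The second pattern is that narrow control peaks were missing far more often than wide ones, 70.4% against 18.2%. Among S2 peaks, too, narrow ones less often had a Kc control peak. On the major arms and within score quintiles, the narrow minus wide difference of control peaks was larger against CP190 RNAi than against S2. The excess was 75.7 points (interval 68.4 to 83.6), and 36.7 points over all sequences. S2 is another cell line and not a repeat library. The excess therefore cannot decide whether narrow peaks are called less repeatably in general. Chance overlap of wide peaks gave 6.88 points of the 52.2 points observed, which argues against random placement as the whole cause. Shifts do not cover wide peaks that are touched by a nearby peak of another site. With centres within 250 bp the observed difference was 25.1 points, so a part may depend on the overlap rule. Longer fragments in the CP190 RNAi library would widen peaks and deplete narrow ones. The 2853 peaks matched singly had a median width ratio of 0.948 (CP190 RNAi over control, interval 0.942 to 0.954). Peaks up to 1025 bp made up 16.9% of the CP190 RNAi list on the major arms against 15.9% in the control (8.69% against 9.57% at a score of 100 or more). These values argue against a general widening of peaks. All matched peaks were kept peaks, with 296 in the narrowest quintile and 780 in the widest. Narrow CP190 RNAi peaks need not lie on narrow control peaks, of which 82.4% were missing on the major arms. Flattening of the missing narrow peaks, or their loss through lower enrichment, is therefore not excluded. As a hypothesis, narrow sites may be those where Gcn5 is brought by CP190 at a point in the sequence, which was not tested, as no CP190 binding data were used here, and other differences between the single libraries stay open.

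The third pattern is that control peaks shared with S2 were missing more often than those not shared. Both were counted on the same control peaks, whose own effect was not simulated. Of the control peaks, 695 were absent from both other lists, against 867 if the absences were independent. Unplaced sequences do not account for the excess, since it was 14.9 points on the major arms (interval 11.5 to 18.5). Differences of width and score between the groups do not account for all of it. Within quintiles of both it averaged 21.0 points (16.9 points on the major arms). The widest quintile gave no such excess, with 17.4% of S2-shared and 19.8% of other peaks missing. A preparation common to both GFP RNAi libraries and not to the CP190 RNAi library cannot be told apart from CP190 depletion with 1 library per condition and line. The same holds for processing common to both Kc lists and not to S2, since peaks it produced would be kept and not shared. The S2 list differs from both Kc lists in its sequence names. Off the major arms lay 8.77% of Kc control, 9.93% of CP190 RNAi and 1.54% of S2 peaks. A candidate explanation is that sites occupied in both lines rest on CP190 more than sites found in Kc alone, and this remains untested.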
